A study of Mus musculus with 2 samples.

How the data were processed

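The samples were 2 biological replicates of embryonic facial prominence from pooled male and female mouse embryos at embryonic day 14.5, profiled by DNase-seq. For each replicate the authors deposited a list of peaks and a list of hotspots in mm10 coordinates. Per the description deposited with each list, peaks and hotspots were derived separately for each replicate from its own filtered alignments and were not pooled. The aligner, the caller, its version, its false discovery rate setting and the read depth are not given in the sources used here. Sequencing instruments are listed, per the labels, for replicate 1 only, so a sequencing batch could not be separated from the replicate.

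The deposited peak lists hold regions of 150 bp with the authors' score for each peak, a whole number from 1 to 150. No normalization is stated for it, and it never exceeded 150 and had medians of 150 and 143 on mitochondrial DNA, with minima of 122 and 109. It was therefore used only to rank peaks within a list, to describe peaks and to choose stronger ones. Median scores were 50 in replicate 1 (quartiles 38 and 69) and 37 in replicate 2 (quartiles 26 and 55). The deposited hotspot lists hold a value that the authors' broad peak format defines as the −log10 of a q-value, starting at 1.30 and ending at 100, a ceiling shared by the strongest class (31.3% of hotspots in replicate 1 and 29.2% in replicate 2). The number and strength of called regions depend on read depth, so a longer list can hold weaker regions, and a region missing from a list is not shown to be closed.

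Regions off chromosomes 1 to 19, X and Y were left out (233 and 213 distinct peaks, of which 30 and 31 lay on mitochondrial DNA) and repeated coordinates (23 and 28) were kept once, which left 304233 and 217980 peaks and 277933 and 198482 hotspots. Peaks covered 1.66% and 1.18% of the main chromosomes, and hotspots 3.18% and 2.19%. The reference was the GRCm38 sequence, the same coordinates as mm10, with the basic GENCODE M21 annotation. No region passed the end of a chromosome and 0 touched a gap of 1000 bp or more. Coordinates are 1-based.

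A peak or hotspot counted as shared when it overlapped 1 bp or more of the other replicate's list, and overlapping shared peaks were merged into sites. Chance overlap came from 100 circular shifts of 1 list within chromosomes. Promoters were windows of 500 bp around transcription start sites, other sites were assigned to exon, intron or intergenic sequence by their midpoint, and distal sites lay over 1000 bp from every start site. Each distal site was given to the protein-coding gene with the nearest start site. The territory of a gene is the sequence nearest to it in that sense, and 21640 genes had at least 1000 bp of it, with a median of 47.1 kb. A distance does not show which gene a site acts on.

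Before the data were examined, 28 gene lists were fixed from general knowledge. Of these, 20 were of the dissected region or of cells it can hold (mesenchymal transcription factors, palate, signalling, Hox, cartilage, bone, tooth, epithelium, skeletal muscle, neurons, glia, endothelium, pericytes and smooth muscle, erythroid, macrophages, lymphocytes, melanocytes, nasal, pituitary and housekeeping) and 8 were comparison lists (hepatocytes, cardiomyocytes, nephron, pancreas and intestine, lung, germ cells, retina and olfactory receptors). Of 604 listed symbols, 1 (Ahsp) was not matched in the annotation used. Some lists share members. Promoter shares were compared with all other protein-coding genes by a two-sided Fisher's exact test, with exact (Clopper-Pearson) 95% intervals that cover counting error only. Distal densities were compared with 10000 random lists of the same size matched on deciles of territory length. Their genes were drawn with replacement within deciles, and the two-sided empirical p from these lists is called a permutation p here. Random lists matched on promoter CpG content were drawn in the same way. Motifs were 34 consensus strings searched on both strands of 150 bp windows at the centre of 140270 distal sites (1 site with an unread base was left out) and of 245499 windows at 1000 bp on either side that overlap no peak or hotspot, compared by Fisher's exact test. Benjamini-Hochberg adjustment was made over lists or motifs, and an adjusted p below 0.05 was called.

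Genes to be named were also fixed before the data were examined. They are, in each list, the 3 members with most shared distal sites and up to 3 members without a shared promoter site (in comparison lists, with one); the 25 genes with most shared distal sites; the 15 genes with the highest ratio to the number expected from territory length among those with at least 20 sites; the genes nearest to the 10 shared peaks of highest mean rank; and the Hox genes as 4 clusters. Other genes named, namely those of the Dlx and Zic pairs and those in neighbourhoods of replicate-only peaks, were chosen after their values were seen.

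Alternatives fixed before the data were examined were a reciprocal overlap of 50%, the stronger part of each list by score, lists of equal length, autosomes only, a promoter window of 1000 bp, hotspots in place of peaks, the gene body with 50 kb on either side, random lists without matching, flanks at 5000 bp, random windows matched on GC content, leaving out the top 1% of peaks, and each replicate alone. Added after the data were seen were the strongest hotspot class alone and random lists matched on promoter CpG content. Also devised after the data were seen were the tests of replicate-only peaks. Distal peaks absent from the peaks and hotspots of the other replicate were compared between gene neighbourhoods with at least 10 distal peaks, given each peak's score, by a one-sided exact binomial test, and CTCF motif content, ranks of shared sites, repeat content, GC content and placement were compared between classes of peaks. Several ways of looking at replicate-only peaks (shares per list, differences per gene, GC content and score) were tried before these were chosen.

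The steps were tested on simulated data. For distal densities over 21640 genes, 82 of 100 random lists given a 2-fold higher density were called at an unadjusted p below 0.05, and 5 of 100 lists with no effect. All 13102 planted overlaps and all planted motif matches were found. For neighbourhoods, among 5217 genes of replicate 2, 44 of 50 genes given a 3-fold excess were called. In a separate run with no excess planted, 0 genes were called. Both runs drew each peak independently, so they do not cover false calls from linked neighbouring peaks. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1.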

Results

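DNase-seq maps open chromatin by digesting accessible DNA in nuclei with DNase I and sequencing the ends of the released fragments. It was applied to embryonic facial prominence, the tissue that builds the face, from mouse embryos of strain B6NCrl at embryonic day 14.5, with males and females pooled. The single group held 2 biological replicates, which came from separate tissue samples under the same donor record. No treatment or other tissue was part of the design, so the comparisons were between the replicates, and between gene groups and sequence motifs within the regions that both replicates shared. Replicate 1 had 304489 peaks and 278129 hotspots, and replicate 2 had 218221 peaks and 198656 hotspots. Peaks were 150 bp wide, and hotspots were broader regions with a median width of 241 bp in replicate 1 and 229 bp in replicate 2. Read counts were not given, so the depth of each library is unknown. With 2 replicates of 1 group no p-value across replicates was possible, and the p-values over genes and sites describe these 2 libraries only, since genes and sites are not independent replicates.

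The first comparison asked how far the open regions of the replicates coincided. The 10 shared peaks of highest mean rank all lay at promoters. The highest mean rank belonged to the promoter of Hjurp, the chaperone that loads the centromeric histone variant, at chromosome 1:88277556-88277705 (mm10), where the authors' score was 150 in replicate 1 and 146 in replicate 2. The promoters of Fam76b, Dnpep, Usp22, Map3k3, Sptlc2, Cdk5, Eif4g2, Cdkn2d and Hdac4 followed, with scores of 148 or 149 in replicate 1 and 141 to 145 in replicate 2. These peaks lay within 282 bp of an annotated transcription start site. After peaks off the main chromosomes were set aside, 59.2% of 304233 peaks of replicate 1 overlapped a peak of replicate 2, and 83.6% of 217980 peaks of replicate 2 overlapped a peak of replicate 1. When the list of the other replicate was shifted along the chromosomes 100 times, the overlap averaged 2.47% and 3.49%, with maxima of 2.57% and 3.63%.

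The share of shared peaks followed the score. In replicate 1 it went from 18.8% in the lowest decile of scores to 98.6% in the highest, and in replicate 2 from 47.1% to 98.8%. The median score of shared peaks was 62 in replicate 1 against 39 for its other peaks, and 40 against 24 in replicate 2. Across 180177 pairs of overlapping peaks, which are not independent replicates, the scores correlated with Spearman's rho of 0.833 and Pearson's r of 0.846 on the log2 scale. For hotspots, 59.3% of replicate 1 and 87.1% of replicate 2 overlapped the other list, against 4.44% and 6.27% by shifting. Peaks covered 45.2 Mb in replicate 1 and 32.2 Mb in replicate 2, with 40.8% of the joint length in both. Chromosome X held 42.9 peaks per Mb in replicate 1 and 29.0 in replicate 2, against 120.5 and 86.5 on the autosomes. With the longer list limited to its strongest peaks so that both had the same length, the overlap was 72.7% for replicate 1 and 73.7% for replicate 2.

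**Figure D1:**
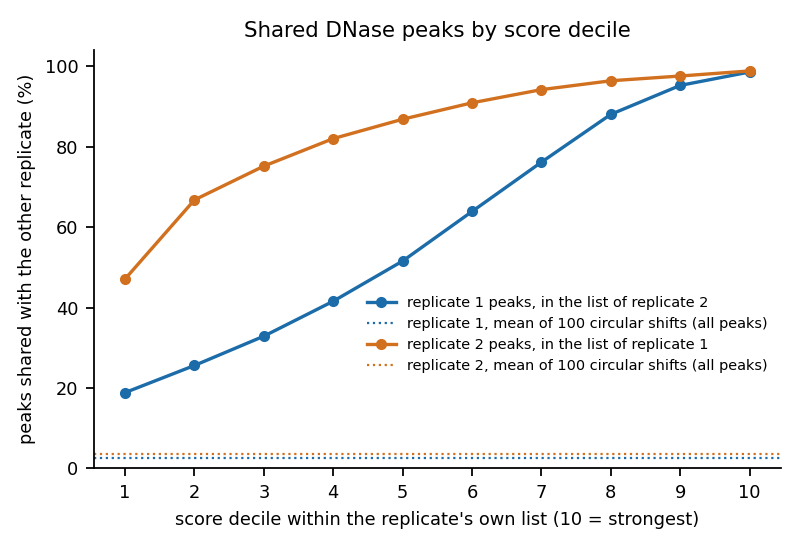
Percent of peaks shared with the other replicate (vertical axis) in each decile of the authors' score within the replicate's own list (horizontal axis), with dotted lines for the overlap after circular shifts. The share went from 18.8% to 98.6% in replicate 1 and from 47.1% to 98.8% in replicate 2.

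Promoters were the most over-represented part of the genome among shared regions. The shared peaks merged into 177440 sites, of which 14.7% lay within 500 bp of a transcription start site, while such windows made up 2.28% of the genome, a 6.44-fold difference. Introns held 43.8% of the sites and 41.2% of the genome, exons 4.27% and 3.22%, and intergenic sequence 37.2% and 53.3%. Among the merged peaks of replicate 1 alone the promoter share was 10.8%, and among those of replicate 2 alone 14.2%. Among the stronger peaks of both replicates the promoter share of shared sites was 22.5%. Of 21824 protein-coding genes, 67.5% (14737 genes) had a shared site at a promoter.

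The next comparison asked which gene groups had open promoters. Transcription factors of the facial mesenchyme, the loose tissue that forms facial bone, cartilage and connective tissue, had shared promoter sites at 43 of 46 genes (93.5%, exact 95% interval 82.1 to 98.6%). The 3 genes without one were Dlx1, a homeobox gene, Foxf2, a forkhead gene of palate mesenchyme, and Hand1, a bHLH gene. At Dlx1 and Foxf2 replicate 1 had promoter peaks with scores of 62 and 65 where replicate 2 had none, and Hand1 had none in either replicate. Genes of palate development and clefting had shared promoter sites at 34 of 37 genes, with Shh, Tbx1 and Vax1 as the exceptions. Shh, which encodes a secreted signal of the facial epithelium, had a promoter peak in replicate 1 only, with a score of 45, and Tbx1 one with a score of 55. Craniofacial signalling genes, some of which also belong to the palate list, had shared promoter sites at 29 of 31 genes, with Shh and Fgf8 as the exceptions. Among the other protein-coding genes the share was 67.5%. The adjusted p was 0.00019 for the mesenchymal transcription factors, 0.0014 for the palate genes and 0.0017 for the signalling genes (two-sided Fisher's exact test against all other protein-coding genes, Benjamini-Hochberg over 28 lists).

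Markers of epithelium and of neurons were open at every promoter tested. All 31 genes of the surface and oral epithelium had a shared promoter site (exact adjusted p = 4.2e-05), among them Trp63, the master regulator of stratified epithelium, with scores of 68 and 40, Tfap2c with 107 and 94, and Klf5 with 139 and 123. All 25 neuronal genes had one (exact adjusted p = 0.00032), among them Gap43, a growth cone protein, with scores of 96 and 64, Isl1, a transcription factor of sensory and motor neurons, with 131 and 113, and Rbfox3, a splicing factor of mature neurons, with 55 and 42. All 20 housekeeping genes had one as well (exact adjusted p = 0.0012), including Ywhaz and Eef1a1. In comparison with random genes of like promoter CpG content, a comparison chosen after the data were seen, the calls of epithelium (permutation adjusted p = 0.0011) and neurons (adjusted p = 0.0064) held. Under that comparison the mesenchymal transcription factors (93.5% against 89.2%, permutation adjusted p = 0.53), palate genes (91.9% against 83.6%, adjusted p = 0.19), signalling genes (93.5% against 86.1%, adjusted p = 0.35) and housekeeping genes (100% against 88.0%, adjusted p = 0.13) no longer stood apart.

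The cartilage, bone, tooth and skeletal muscle lists had shared promoter sites at 63.6 to 68.2% of their genes, against 67.5% of all genes. Cartilage genes had shared promoter sites at 17 of 25, among them Sox9, the chondrocyte master regulator (scores of 140 and 116), Sox6 (88 and 62) and Trps1 (115 and 94), while Cnmd, Comp and Col10a1, the collagen of hypertrophic cartilage, had no promoter peak. Bone genes had them at 15 of 22, among them Runx2, the osteoblast master regulator (97 and 99), Col1a1 (122 and 102) and Col1a2 (140 and 121), while Bglap and Bglap2, which encode osteocalcin, and Ifitm5 had none. Tooth genes had them at 14 of 22. The tooth regulators Bcl11b (137 and 125) and Lhx8 (94 and 69) were open, while Amelx and Amtn, which encode enamel proteins, had no promoter peak, and Ambn had one in replicate 1 only. Skeletal muscle genes had them at 19 of 28, with Mef2c, Msc and Ttn open, Acta1 and Ckm with a peak in replicate 1 only, and Lbx1 with a peak in replicate 2 only. The exact adjusted p was 1 for cartilage, bone and muscle and 0.80 for tooth, so none of these lists stood apart from other genes. Against genes of like promoter CpG content the share of bone genes was above its comparison (68.2% against 42.8%, permutation adjusted p = 0.038).

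The lists of glia, pericytes and smooth muscle, endothelium, melanocytes, nasal tissue and cardiomyocytes were not called in either direction, although their shares ranged from 55.6% for cardiomyocytes to 92.3% for pericytes and smooth muscle. Glial genes had shared promoter sites at 12 of 14 (exact adjusted p = 0.35), including Mbp, Foxd3 and Egr2 but not Gfap. Pericyte and smooth muscle genes had them at 12 of 13 (exact adjusted p = 0.11), including Ebf1, Notch3 and Cspg4. The exception was Acta2, smooth muscle actin, whose promoter had a peak in each replicate, with scores of 102 and 53, that did not overlap. Endothelial genes had them at 13 of 22 (exact adjusted p = 0.63), including Cdh5, Emcn and Erg, with Etv2, Mmrn2 and Notch4 among the exceptions. Melanocyte genes had them at 8 of 11 (exact adjusted p = 1), including Dct, Mitf and Tyrp1 but not Pmel, Slc45a2 or Tyr. Genes of nasal and olfactory tissue had them at 12 of 17 (exact adjusted p = 1), including Ebf1, Ebf2 and Ebf3. Cnga2 and Gnrh1 had no promoter peak. Cardiomyocyte genes, a comparison list, had them at 10 of 18 (exact adjusted p = 0.42), including Gata4, Hcn4 and Myh7 but not Tbx5. With replicate 1 alone the endothelial share turned from −8.44 to 10.9 percentage points relative to other genes, and with the stronger part of each list it was called below other genes (31.8%, exact adjusted p = 0.0052), as was the melanocyte list (27.3%, adjusted p = 0.033). The pericyte list was called above other genes with a promoter window of 1000 bp (exact adjusted p = 0.022), with shared hotspots (0.019), and with replicate 1 (0.026) or replicate 2 (0.019) alone.

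The lists of blood lineages and of most organs outside the face had fewer shared promoter sites than other genes. Erythroid genes had shared promoter sites at 6 of 21 (exact adjusted p = 0.00074), with Ank1 open and Gata1, Alas2 and Rhag without a promoter peak. Macrophage and myeloid genes had them at 6 of 20 (exact adjusted p = 0.0018). Of the macrophage genes, Mrc1, C1qa and C1qc had no promoter peak, C1qb and Laptm5 had one in replicate 1 only, and Ptprc one in replicate 2 only. Lymphocyte genes had them at 2 of 19 (exact adjusted p = 3.8e-06), with Cd2, Zap70 and Blk among those without. Pituitary genes had them at 4 of 13 (exact adjusted p = 0.012), with Lhx4 open and the hormone genes Cga, Fshb and Gh without. Hepatocyte genes had them at 2 of 23 (exact adjusted p = 9.1e-08), namely Ahsg and Nr1h4. Nephron genes had them at 7 of 18 (exact adjusted p = 0.031), including Podxl, Pax2, Kcnj1, Lhx1 and Lrp2. Pancreas and intestine genes had them at 4 of 20 (exact adjusted p = 8e-05), including Hnf4g, Ins2 and Pdx1. In the lung list only Foxj1, of 11 genes, had one (exact adjusted p = 0.00031). Germ cell genes had them at 3 of 21 (exact adjusted p = 4.9e-06), namely Dazl, Tdrd1 and Zpbp, and retina genes at 4 of 16 (adjusted p = 0.0013), including Rax, Sag and Opn1mw. Of 1133 olfactory receptor genes, 32 (2.82%) had one, including Olfr1033, Olfr1253 and Olfr1336. Against genes of like promoter CpG content the erythroid (permutation adjusted p = 0.74), macrophage (0.80), pituitary (0.75), nephron (0.19) and retina (0.22) calls ended, while those of lymphocytes, hepatocytes, pancreas and intestine, lung, germ cells and olfactory receptors held. The nephron and pituitary calls also ended with a promoter window of 1000 bp (exact adjusted p = 0.056 and 0.11), and the macrophage call with replicate 1 alone (adjusted p = 0.071).

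**Figure D2:**
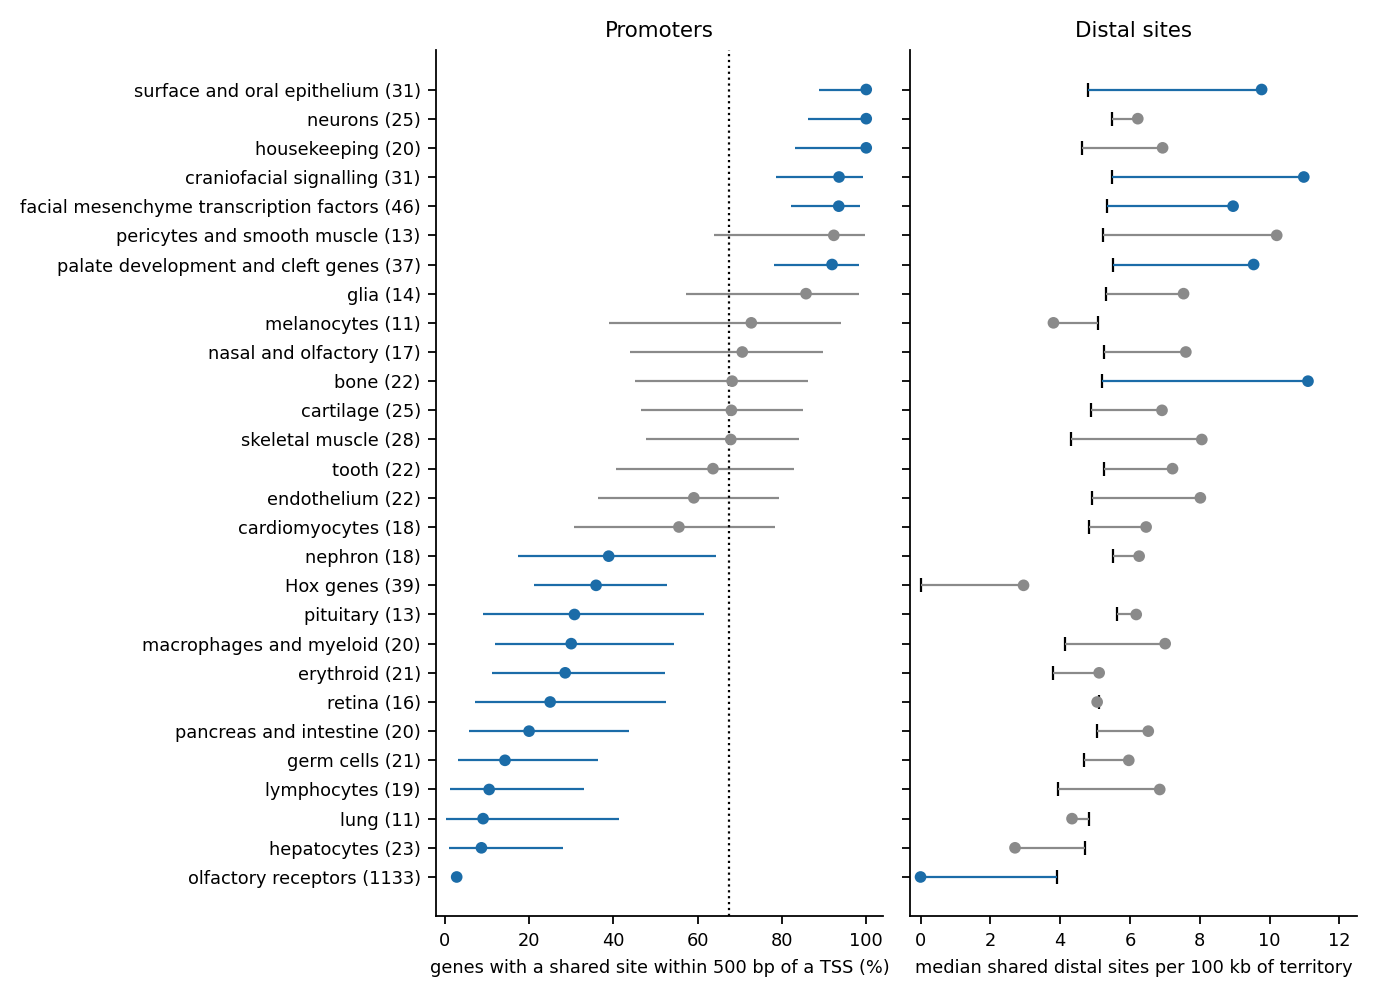
Left, percent of each list's genes with a shared site within 500 bp of a transcription start site, with exact 95% intervals, list sizes in brackets and a dotted line at the share of all genes (67.5%); right, each list's median shared distal sites per 100 kb of territory, joined by a line to a tick at the median of matched random lists. Blue marks an adjusted p below 0.05 and grey the rest, and epithelial, neuronal and housekeeping genes lay at 100% and olfactory receptors at 2.82%.

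Hox genes, which pattern the trunk and the hindbrain, had shared promoter sites at 14 of 39 genes (35.9%, exact 95% interval 21.2 to 52.8%, adjusted p = 0.00019). The call held against genes of like promoter CpG content, where 88.5% was the comparison (permutation adjusted p = 0.0011). Hoxb1, Hoxa2, Hoxa3 and Hoxa11 had no promoter peak and Hoxc4 had one in replicate 1 only. The HoxA cluster (chromosome 6:52155590-52260880, mm10) held 11 shared sites, HoxB (chromosome 11:96194316-96368256) 15, HoxC (chromosome 15:102921103-103036852) 10 and HoxD (chromosome 2:74668310-74765142) 10. These are 10.4, 8.62, 8.64 and 10.3 sites per 100 kb, against 6.51 over the main chromosomes. Hotspots covered 3.95% of HoxA in replicate 1 and 2.66% in replicate 2, 2.92% and 3.20% of HoxB, 3.04% and 2.27% of HoxC, and 3.57% and 3.01% of HoxD, against 3.18% and 2.19% of the main chromosomes.

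Other pairs of developmental genes, chosen after their values were seen, were open over larger parts of their length and in 1 replicate more than in the other. Across Dlx5 and Dlx6 (chromosome 6:6863334-6882085, mm10), homeobox genes that set lower jaw identity, hotspots covered 45.1% in replicate 1 and 20.2% in replicate 2, with 21 and 11 peaks. Across Dlx1 and Dlx2 (chromosome 2:71528113-71546754) they covered 28.7% in replicate 1 and 3.43% in replicate 2, with 18 and 4 peaks. The opposite imbalance was seen at Zic2 and Zic5 (chromosome 14:122456795-122479852), zinc finger genes of the dorsal midline and forebrain, where hotspots covered 9.41% in replicate 1 and 46.8% in replicate 2, with 6 and 38 peaks. With 1 library per side of each difference, none of them has a replicate check.

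**Figure D3:**
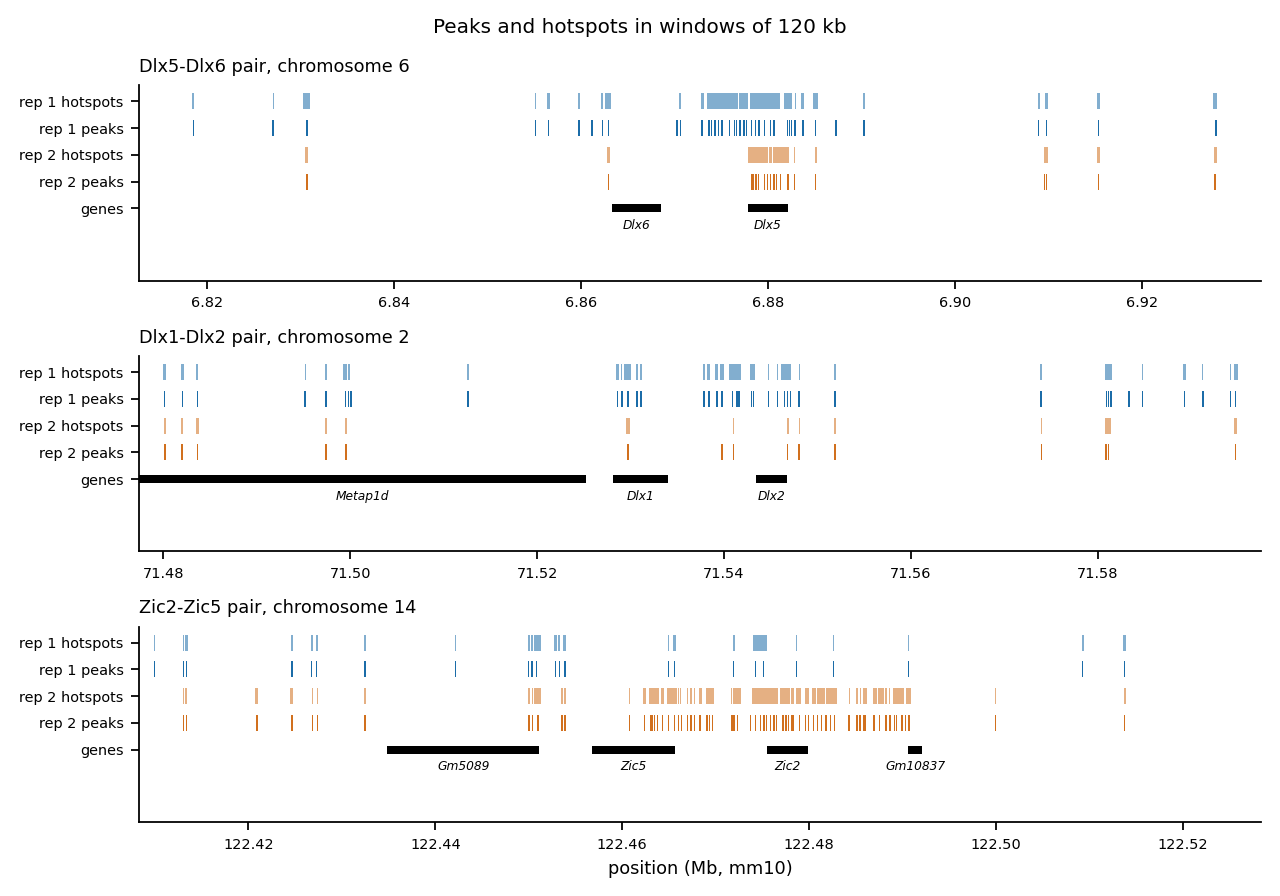
Peaks and hotspots of both replicates in windows of 120 kb around the Dlx5-Dlx6, Dlx1-Dlx2 and Zic2-Zic5 pairs, drawn to scale along mm10 positions in Mb with genes as black bars. Hotspots covered 11.6% of the Dlx5-Dlx6 window in replicate 1 and 5.01% in replicate 2, and 5.49% and 17.0% of the Zic2-Zic5 window.

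The distal regions, over 1000 bp from every transcription start site, were then compared between gene groups. Shared distal sites were denser than around matched random genes for the signalling, bone, epithelial, palate and mesenchymal transcription factor lists. The median density in the territory of a gene, the stretch closer to its start sites than to those of any other protein-coding gene, was 10.98 sites per 100 kb for craniofacial signalling genes against 5.47 for random lists matched on territory length. It was 9.54 against 5.53 for palate genes and 8.96 against 5.35 for mesenchymal transcription factors. For these 3 lists the permutation adjusted p was 0.0014, which rests on a p of 0.0002, the smallest that 10000 random lists can give. Bone genes had 11.1 sites per 100 kb against 5.20 (permutation adjusted p = 0.0022), and epithelial genes 9.77 against 4.81 (adjusted p = 0.0075). Among signalling genes, Cyp26b1, which degrades retinoic acid, had 58 shared distal sites, Gli3, a mediator of hedgehog signalling, 56, and Spry2, an inhibitor of FGF signalling, 55. Fgfr2 had 77 and Tgfbr2 66 among the palate genes, and Tbx3 had 79, Runx1 73 and Zeb2 85 among the mesenchymal transcription factors. The sites of Zeb2 were 0.824 times the number its long territory would give at the genome's mean rate. In the bone list Runx2 had 62, Col1a2 31 and Col1a1 29, and in the epithelial list Trp63 had 35, Tfap2c 31 and Klf5 26.

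Olfactory receptor genes lay at the other end. Of the 1133 genes, 944 had no shared distal site, and the median density was 0 against 3.91 for matched random lists (permutation adjusted p = 0.0014, at the smallest p). With the stronger part of each list alone, the median of the random lists was also at 0 and the call ended. The other 22 lists were not called against matched random lists, which for short lists does not show that no difference exists. Nearest to the threshold were pericytes and smooth muscle (10.2 against 5.22, permutation adjusted p = 0.080) and skeletal muscle (8.06 against 4.31, adjusted p = 0.097), where Ebf1 had 68 sites and Mef2c 74. Endothelial genes had 8.02 against 4.93 (permutation adjusted p = 0.17), with 63 sites around Cdh5, and nasal and olfactory genes 7.60 against 5.26 (adjusted p = 0.27). Cartilage genes had 6.92 against 4.88 (permutation adjusted p = 0.35), with 124 sites around Sox9 and 82 around Sox6. Hepatocyte genes had 2.71 against 4.70 (permutation adjusted p = 0.38), and Hox genes 2.95 against 0 in their short territories (adjusted p = 0.41). Skeletal muscle genes passed the threshold when sites were counted over the gene body and 50 kb on either side (permutation adjusted p = 0.0034), with the stronger part of each list (0.035) and with replicate 1 alone (0.013). Endothelial (permutation adjusted p = 0.026) and housekeeping genes (0.012) passed it only over the gene body, and pericytes only with shared hotspots (0.049).

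Of all protein-coding genes, Auts2 and Zfp608 had most shared distal sites. Auts2, a neurodevelopmental gene, had 193, Zfp608 190, Adgrl2, an adhesion receptor, 175, Zfhx3 158, Tenm3, a teneurin, 152, Efna5, an ephrin, 130, and Sox9 124. Flrt2 had 117, Pde4d 114, Zfp36l1 112, Cdh11, a cadherin of mesenchymal cells, 111, Robo1 111, Rbms3 110, Nfib 107, Ptprd 107 and Tns1 105. The rest of the top 25 were Adgrl3, Sox4, Tbl1xr1, Celf4, Epha4, Cited2, Magi1, Slc4a3 and Sox11, with 99 to 103 each. Relative to territory length the order differed. Zfp36l1 had 4.39 times and Tns1 3.04 times the number that their territories would hold at the genome's mean rate of 5.30 sites per 100 kb, whereas Flrt2 had 0.689 times and Adgrl3 0.623 times that number.

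Relative to territory length, the highest counts among the 1901 genes with at least 20 shared distal sites were at genes with territories of 28.1 to 103 kb. Gm21887, a predicted gene on chromosome X, had 16.8 times the expected number. Rara, a retinoic acid receptor, had 32 sites where 2.85 were expected (11.2 times), Faap20 7.97 times, Ddit4, a stress-response gene, 7.66 times, Tex44 7.51 times, Kdm6b, a histone demethylase, 6.97 times, and Id3, an inhibitor of bHLH factors, 6.34 times the expected number. Genes known in craniofacial development among those with the highest ratios included Col1a1 with 29 sites (5.92 times), Notch1 with 21 (5.84 times) and Fstl1 with 31 (5.66 times). Mrpl23, Bahcc1, Trim27 and Trim8 lay at 5.57 to 6.03 times. Tex44 had no promoter peak in either replicate.

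The last comparison within the shared regions asked which transcription factor motifs the distal sites held. Motifs of CTCF, NFI, RFX and REST were far more frequent in the sites than in the flanking windows. Those of myogenic, GRHL, TEAD, RUNX and TWIST factors were also more frequent in the sites than in the flanks. The CTCF motif, which marks insulators, occurred in 4.06% of 140270 distal sites and in 0.0415% of 245499 flanking windows, an odds ratio of 102 (95% interval 83.8 to 124) that was 63.5 with replicate 1 alone and 176 with the stronger part of each list. The REST motif, bound by a repressor of neuronal genes, occurred in 148 sites and in 0 flanking windows. Odds ratios were 53.4 (30.03 to 94.9) for the NFI palindrome (35.2 with flanks at 5000 bp) and 23.6 (8.56 to 65.3) for RFX (36.6 with replicate 1 alone), with 365 and 54 sites. The motif of GRHL factors, which drive epithelial genes, had an odds ratio of 6.67 (5.03 to 8.84) and the myogenic motif of MYOD and MYOG one of 5.59 (5.19 to 6.02). The odds ratio was 2.42 (2.29 to 2.55) for TFAP2, 2.30 (2.23 to 2.37) for TEAD and 2.19 (2.10 to 2.29) for RUNX. The E-box CATCTG bound by TWIST and other bHLH factors was in 18.7% of sites and 11.3% of flanks, an odds ratio of 1.81 (1.78 to 1.85). Its composite with a homeodomain site, called Coordinator, was found in 39 sites, at an odds ratio of 1.59 (1.03 to 2.45, exact adjusted p = 0.047). That call ended with replicate 2 alone (exact adjusted p = 0.15) and with the stronger part of each list (adjusted p = 0.58).

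In all, 22 of 34 motifs were more frequent in sites than in flanks, 6 were less frequent and 6 did not pass (Fisher's exact test, Benjamini-Hochberg over motifs). Further motifs above 1 included PU.1 of myeloid cells at 3.96, SP/KLF at 3.56, NRF1 at 3.41 (5.42 with flanks at 5000 bp), MEF2 at 2.12, the retinal CRX motif at 2.01, ETS at 1.94, AP-1 at 1.77, PBX/MEIS at 1.72, GLI at 1.51 and SOX at 1.08. Those below 1 were HNF1 of endoderm and kidney at 0.250 (4 sites, and 0.131 with replicate 1 alone), GATA at 0.518, posterior HOX at 0.646, FOX at 0.868, the homeodomain core TAATTA at 0.880 and PITX/OTX at 0.956. YY1 (2.04, 14 sites), HNF4 (0.851, exact adjusted p = 0.051), NFY (0.972), LEF/TCF (1.00), TP63 (0.962) and the SOX9 dimer (2 sites) did not pass. The sites had a GC content of 49.1% and the flanks 43.8%. Against random windows of equal GC content TAATTA turned to 2.04 and FOX to 1.47, and the GLI, HNF1 and PITX/OTX calls ended (exact adjusted p = 0.46, 0.44 and 0.78). In that comparison MEF2 went to 4.66 and Coordinator to 3.25, while GRHL went to 3.23, MYOD and MYOG to 3.55, SP/KLF to 2.25 and TFAP2 to 1.33. NFY was called below 1 in that comparison (0.676), with flanks at 5000 bp (0.905) and with replicate 1 (0.933) or replicate 2 (0.968) alone. With flanks at 5000 bp HNF4 was called below 1 and YY1 above it (exact adjusted p = 0.00100 and 0.033), as they were with replicate 1 alone for HNF4 (0.00084) and replicate 2 alone for YY1 (0.0036). LEF/TCF was called above 1 against windows of equal GC content (1.10) and with replicate 1 alone (1.08), and below it with the stronger part of each list (0.875).

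**Figure D4:**
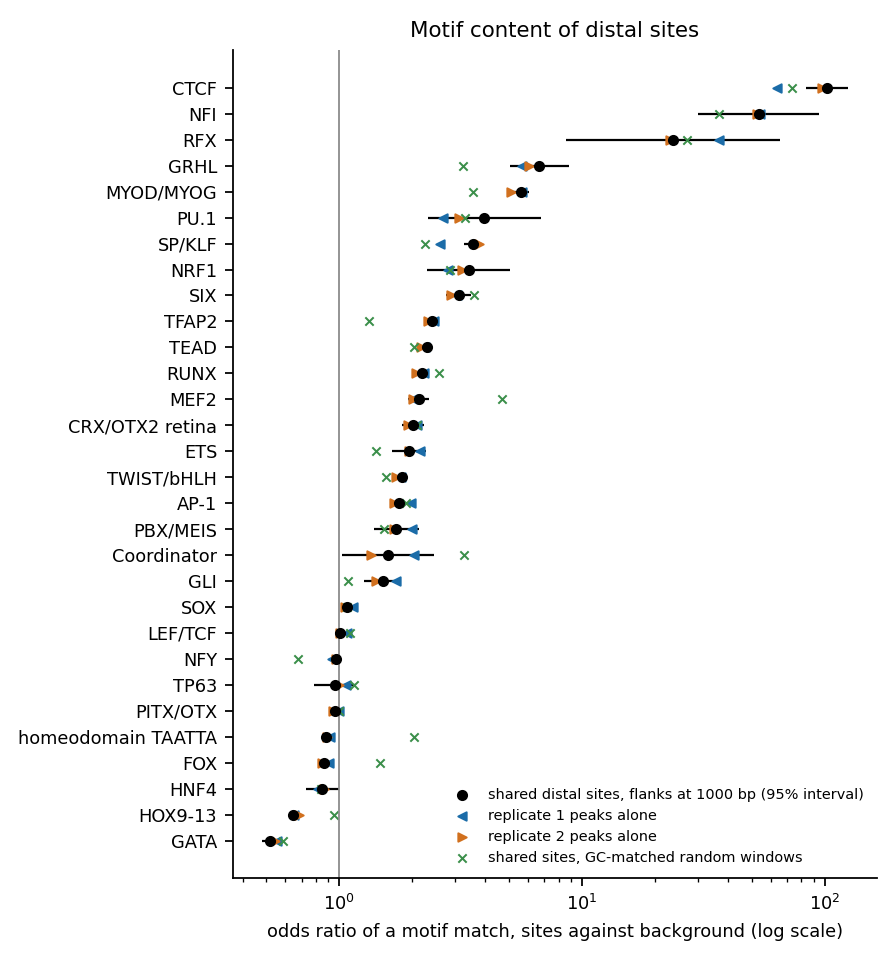
Odds ratio of a motif match in distal sites against background windows on a log axis, for shared sites against flanks at 1000 bp (black, with 95% intervals), for each replicate alone (triangles) and for shared sites against random windows matched on GC content (crosses). CTCF lay at 102, GATA at 0.518, and TAATTA at 0.880 against flanks and 2.04 against matched windows; motifs with fewer than 20 sites or no background match are left out.

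Peaks found in a single replicate differed between the replicates in where they lay. Of the peaks of replicate 1 only, 5.12% lay within 500 bp of a transcription start site, 48.3% in introns and 42.4% in intergenic sequence. Of the peaks of replicate 2 only, 11.4% lay at promoters, against 14.7% of shared peaks in either list. With both lists at equal length the promoter share was 6.62% for replicate 1 only and 9.32% for replicate 2 only, against 15.9% and 15.8% of shared peaks. With a promoter window of 1000 bp the share for replicate 2 only (20.3%) was no longer below that of shared peaks (20.2%), while that for replicate 1 only remained below (8.97% against 20.3%). The peaks of 1 replicate only include some inside a hotspot of the other, namely 5.38% in replicate 1 and 27.5% in replicate 2. Peaks that lay in neither the peaks nor the hotspots of the other replicate numbered 117386 in replicate 1 (38.6% of its list) and 25968 in replicate 2 (11.9%). Of these, 3.92% and 8.06% reached within 500 bp of a transcription start site with any part of the peak. By the same measure 15.8% and 15.7% of shared peaks did.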

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

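The results rest on lists of regions from 2 libraries of unknown depth, so they do not show how far embryos differ, and tests over genes or sites take these as independent although neighbours are not. The strongest hotspot class and the match on promoter CpG content were chosen after the data were seen, and the other settings before. Under all planned settings both the call and the direction were kept by 19 of 28 lists for promoters, 16 of 28 for distal density and 22 of 34 motifs. All lists and motifs that reversed direction are given here with their values, and where a result moved, the cause was not tested.

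With both lists at equal length the peak overlap was 72.7% for replicate 1 (59.2% in full) and 73.7% for replicate 2 (83.6%), and the promoter share was 6.62% for peaks of replicate 1 only, 9.32% for those of replicate 2 only, and 15.9% and 15.8% for shared peaks, so the order of the classes was kept. Requiring overlap of 50% of both regions gave 55.3% and 77.6% of peaks and 46.9% and 65.7% of hotspots, with Spearman's rho at 0.836 and Pearson's r at 0.849 for the paired scores. Without the top 1% of peaks of each list these were 0.822 and 0.830. The strongest hotspot class alone, added after the data were seen, overlapped by 59.8% and 90.0%. A promoter window of 1000 bp gave a promoter share of 20.2% for shared sites, and of 8.97% (replicate 1 only), 20.3% (replicate 2 only), 20.3% and 20.2% (shared) for peaks, where replicate 2 only no longer lay below the shared peaks.

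With the stronger part of each list by score, 63.6% and 88.9% of peaks and 63.2% and 89.6% of hotspots were shared, and the promoter share of shared sites was 22.5%. Distal density then had 0 lists below matched random lists instead of 1. The percentile among random lists turned for Hox genes (49.6 from 86.7), erythroid (34.7 from 68.5), germ cells (49.3 from 72.9), lymphocytes (34.3 from 89.9), pituitary (48.3 from 61.0) and retina (90.6 from 48.9), none of which was called in either. For promoters the difference from other genes, in percentage points, turned for bone (−4.13 from 0.656), cartilage (−7.22 from 0.474), melanocytes (−36.0 from 5.20, then called below other genes) and muscle (−6.08 from 0.331). The odds ratio was 0.875 for LEF/TCF (1.00 before) and 1.02 for NFY (0.972 before).

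Counting over the gene body with 50 kb on either side put 8 lists above random lists instead of 5, and the percentile turned for Hox genes (46.0), erythroid (46.0), neurons (37.4 from 74.2) and retina (90.2). Random lists without matching turned Hox genes (6.22) and retina (54.0). Shared hotspots turned the distal percentile of erythroid (39.1) and retina (52.1) and the promoter difference of cartilage (−0.173) and muscle (−0.316). Matching on promoter CpG content turned cartilage (−4.13), nasal (−9.70 from 3.06) and tooth (4.48 from −3.89), and left 3 lists above (6 before) and 7 below (12 before).

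For motifs, flanks at 5000 bp turned LEF/TCF (0.984) and TP63 (1.05 from 0.962). Windows matched on GC content turned FOX (1.47 from 0.868), the SOX9 dimer (5.0 from 0.70), TP63 (1.15) and TAATTA (2.04 from 0.880), and left 3 motifs below instead of 6, of which NFY (0.676) was newly called.

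With replicate 2 alone and replicate 1 alone, in that order, the promoter share was 14.2% and 10.8%, and the distal percentile of erythroid genes 49.6 and 23.5. The promoter difference was −0.500 and 1.78 points for bone and −9.60 and 10.9 for endothelium (−8.44 in shared sites). The odds ratio was 0.939 and 1.00 for PITX/OTX (0.956 in shared sites) and 0.995 and 1.07 for TP63.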

Other observations

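All tests of replicate-only peaks in this part were chosen only after the results they concern were seen. Around some genes more distal peaks of 1 replicate than expected from their scores lay where the other replicate had neither peak nor hotspot. In replicate 2 the gene neighbourhoods of Zic5 and Zic2 had 14 of 14 and 17 of 19 distal peaks in replicate 2 only, where 3.63 and 4.76 were expected from the scores. Zic5 and Zic2 are adjacent on chromosome 14, so their neighbourhoods are parts of a single region. The neighbourhoods of Meis2 (43 of 100), Nr2f2 (54 of 153), Sp9 (21 of 33), Emx2 (18 of 42) and Otx1 (25 of 48) followed. Bmp7, which encodes a secreted signal, was called in both replicates. Of the facial mesenchyme transcription factors, 7 of 36 tested were called, including Alx4, Msx1, Foxd2, Pitx1 and Meis2, in replicate 2, which is 19.4% against 0.849% of other genes (Fisher's exact test, adjusted p = 7.5e-07). Among nasal and olfactory genes, Ebf2, Ebf3 and Emx2 were called (3 of 13, adjusted p = 0.0023 by the exact test).

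In replicate 1 the largest counts of replicate-only peaks among called genes were around Auts2 (168 of 368, 131 expected) and Foxp1, a forkhead gene (106 of 193, 72.8 expected). Of all distal peaks of replicate 1, 42.8% were absent from the peaks and hotspots of replicate 2. Lrig1, an inhibitor of growth factor receptors, had 48 of 84 distal peaks in replicate 1 only (21.6 expected), Rad51b 69 of 136 (35.7 expected) and Tcf7l1, a repressor in the Wnt pathway, 26 of 40 (8.50 expected). Ror2 had 29 of 50, Tbx15 32 of 45 and Gsc, a homeobox gene of the jaw mesenchyme, 37 of 51 (adjusted p = 0.0032, exact binomial test). No gene list was called for replicate 1, where the mesenchymal transcription factors had 2 of 40 genes (Gsc and Runx1, exact adjusted p = 0.92).

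Peak strength and list length might account for such neighbourhoods, since replicate 1 has the longer list. With the score of every peak taken into account, 85 of 6836 genes in replicate 1 and 51 of 5217 in replicate 2 had an excess of replicate-only peaks. Some called genes are adjacent, such as Zic2 and Zic5, so these are counts of genes and not of separate regions. No gene was called in any of 100 shuffles (highest 0). The shuffles kept the score deciles that gave the expected numbers and broke any link between neighbouring peaks, so few calls were built in. They cannot decide whether strength or list length acts on groups of neighbouring peaks. Masked repeats are unlikely to account for these neighbourhoods as a set. Their replicate-only peaks had −0.662 percentage points of repeat-masked sequence relative to shared distal peaks in replicate 1 and 1.22 points in replicate 2. These means cannot exclude repeats at single genes. The highest mean among genes called in replicate 2 was at Sfi1, whose 14 peaks of replicate 2 only were 55.0% masked, against 9.35% for shared distal peaks. Duplicated sequence that is not masked was not examined. GC content could separate libraries, but the mean GC of the peaks in replicate 1 minus that in replicate 2 was −0.758 points. Within each replicate these peaks had a higher GC content than other replicate-only peaks. The means were 49.8% against 47.8% in replicate 1 and 50.5% against 46.5% in replicate 2. Means over called genes cannot settle a part of GC content within a replicate or at single genes. A difference in the dissected tissue was not tested, because the design holds no biological group to compare.

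CTCF sites were almost absent from the distal peaks of replicate 1 only, where 0.153% of 62565 peaks held the motif against 3.04% of shared peaks matched on score. That odds ratio was 0.0490 (95% interval 0.0399 to 0.0601), and matching on GC content as well gave 0.0494, so neither peak strength nor GC content is likely to account for it. In replicate 2 the odds ratio matched on score was 2.69 (95% interval 2.24 to 3.23), whereas over all its distal peaks, without matching, those with the motif were shared more often (92.8%) than those without (83.3%). Shared CTCF sites ranked 6.99 percentile points higher in replicate 2 than in replicate 1 in the median, against −9.95 for other sites; REST sites differed from others by 18.3 points, promoter sites by 8.37 and SP/KLF sites by 6.62, and MYOD and MYOG sites by −5.31. The difference of 16.9 points (95% interval 16.6 to 17.3) includes an effect of the longer list of replicate 1 on ranks of unknown size. It is largely the same imbalance between the replicates, seen at shared sites, so it is not independent evidence for a cause. A different balance of signal between the libraries may account for part of the pattern, but these ranks cannot decide that. No biological explanation was tested.

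Strong peaks listed in 1 replicate only may seem to be replicate-specific sites, but those of the highest scores lay mostly in regions open in both. Of the 438 and 256 peaks of 1 replicate only in the top decile of scores, at least 95.7% in either replicate lay inside a hotspot of the other, against 5.38% and 27.5% of all peaks of 1 replicate only. In the next decile the share was 56.4% in replicate 1 and 97.9% in replicate 2. Within the top decile the share is in line with 150 bp windows placed differently inside a region open in both, although only 71.5% and 75% of these peaks had a peak of the other replicate within 150 bp.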
